A study of Arabidopsis thaliana with 24 samples.

How the data were processed

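The study measured transcripts in Arabidopsis thaliana of the Columbia accession with Affymetrix arrays, 1 array for each of 24 RNA samples. Per the labels' protocols, 100 ng of total RNA from each sample was amplified and labelled with biotin from the 3' end. The samples fall into 12 groups of 2 arrays, 3 harvests by 4 waterings, and the group and the replicate number of each array were taken from its title. The labels name 2 replicates of each group without saying whether they came from separate pots or batches, so p-values measure only the spread between these samples, which may be technical.

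The deposited values are 1 signal per probe set and array. Per the submitters' processing notes they were made with Affymetrix Expression Console; its version and the summary algorithm are not given in the sources used here. The deposited values are intensity on a linear scale, which was settled from the values themselves. Each array's mean after trimming 2% at each end lay between 500.044 and 500.055, as it does after scaling every array to a target of 500, and the lowest value on every array was 1. Array medians ran from 154 to 192, a range of 0.30 on the log2 scale, so no further normalization was added. Between 39.4% and 43.7% of probe sets on an array lay under a signal of 100. The number of arrays, 2 per group, limits the precision of every value.

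From these intensities log2(signal + 16) was computed, so a fold change is on the log2(value + 16) scale and understates the change of dim probe sets. The 64 Affymetrix control probe sets were left out and the other 22746 were tested without a filter. A linear model with 1 mean per group was fitted to all 24 arrays at once with limma 3.58.1 in R 4.3.3, which leaves 12 residual degrees of freedom per probe set, and the variances were moderated with an intensity trend (prior degrees of freedom 7.39). Each contrast was adjusted by the Benjamini-Hochberg method over the 22746 probe sets, and a probe set with an adjusted p under 0.05 was called. Each fed solution was compared with water at each harvest and over the unweighted mean of the 3 harvests, the solutions were compared with each other, the effect at 5 weeks was compared with that at 4 weeks, and the leaf blades of 5 weeks were compared with those of 4 weeks over all 4 waterings. Levels are given as the mean signal ± SD of 2 arrays. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 was used for tables and plots.

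Genes were named through the platform annotation given with the series, with symbols updated by gene identifier to the TAIR10.1 reference. Of the probe sets tested, 13513 had 1 gene, 503 had several and 8730 were unnamed here, and 13436 of the first kind matched the reference. A gene to which the reference gives no symbol is written with its locus tag. No coordinates were used. The genes named for a contrast are those past the threshold with 1 gene, a higher group mean above the 40th percentile of all probe sets and every array of one side beyond every array of the other within each harvest: the largest changes up and down, 10 each for the 3 means against water and for leaf age, 5 each otherwise. Where fewer than 3 genes met this, the 5 with the smallest p are named and said not to have met it. Up to 4 members of each gene list past its test, and of the sulfur, glutathione and nitrogen lists in any case, are named as well.

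Gene lists written before the data were examined, 26 in all with 541 members, cover sulfur and nitrogen use, redox genes, photosynthesis, hormones, stress, secondary metabolism and markers of other tissues. Only 86 members had a probe set with 1 gene, because many probe sets of well-known genes were unnamed here. The 12 lists with at least 3 measured members were tested with camera at a preset correlation of 0.01, on the brightest probe set of each gene, in 16 contrasts, with Benjamini-Hochberg adjustment over the lists of a contrast; this minimum was chosen after the coverage was seen. The other 12 lists with a measured member are reported gene by gene, and 2 lists had none. A list of cytosolic ribosomal proteins was not tested because it was defined by gene descriptions, which the reference used here lacks. Camera was run again with a correlation estimated for each list. Gene families sharing a symbol prefix, and the chloroplast genome, were added after the data were seen.

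The groups, tests, named-gene rule, gene lists and first set of alternatives were fixed before the data were examined. The alternatives were quantile normalization, centring on array medians, leaving out probe sets under the 40th percentile, pseudocounts of 1 and 64, a prior without trend or a robust one, a replicate block, only the arrays compared, only the 4 and 5 week harvests, and leaving out each array. Whether replicate numbers pair the samples was checked from the correlation of same-numbered arrays' deviations from their group means over probe sets above the 40th percentile. Each comparison gave 1 correlation for each of the 3 harvests. With 2 arrays per group, the replicate 2 pair only repeats the replicate 1 pair. The correlations ran from 0.176 to 0.394 for GSSG and water and from 0.234 to 0.37 for GSH and water. They ran from 0.182 to 0.346 for NH4NO3 and water, from 0.171 to 0.268 for GSSG and GSH and from 0.249 to 0.399 for GSH and NH4NO3. All of these were above 0.1, and the numbers were taken to pair those samples. For GSSG and NH4NO3 the lowest was 0.0487. The pairing comes from the data and the titles' numbers, since no label says what the numbers share.

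The scripts were tested on simulated data made from these arrays with 200 changed genes. For GSH against water at 5 weeks, 24% of genes changed by 1 on the log2 scale were recovered, 74% of those changed by 2 and 100% of those changed by 4, and 8 of 22546 unchanged genes were called. Over the mean of 3 harvests, 70% of genes changed by 1 were recovered. For leaf age 80% were. For GSH against water at 5 weeks a list of 10 genes shifted by 1 was found while none of 20 unshifted lists was called. The simulated values were drawn independently for each gene and array, with the same spread at all harvests. They held no correlation between genes or between same-numbered arrays. The unshifted lists therefore say nothing on false calls among correlated genes, and the recovery rates apply to such independent values.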

Results

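The series set out to describe how feeding glutathione changes the transcripts of Arabidopsis. Glutathione is a tripeptide thiol that plants use as a redox buffer and a store of reduced sulfur. Its oxidized form, GSSG, is a pair of reduced molecules, GSH, joined by a disulfide bond. Pots received 25 ml of solution from below once a week, from week 1 to week 5. The solutions were water (the control), 1 mM GSSG, 2 mM GSH and 3 mM NH4NO3, the last written with its atoms in another order in the labels' protocol. The doses of GSSG and GSH are equal in glutathione units, and each of the 3 fed solutions holds 6 mM nitrogen. Aerial parts with the shoot apex were taken at 3 weeks (3W). The second and the third fully expanded leaf blades were taken at 4 weeks (4W) and 5 weeks (5W). Each of the 12 groups had 2 arrays, all scaled to the same trimmed mean signal of 500. The ratio of 3' to 5' signal of the actin control, a sign of RNA integrity, was between 4.29 and 4.81 on the 4 replicate 2 arrays at 4W and between 2.65 and 3.80 on the other arrays. Those 4 arrays also had the highest signals of the cre spike, from 44895 to 61671.

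In aerial parts at 3W no gene passed the test against water with any solution. The named genes with the smallest p, which did not meet the rule, were AT1G48750 with GSSG (log2 change 0.59 ± 0.14 (SE), adjusted p = 1), AT5G53030 with GSH (-1.59 ± 0.35, adjusted p = 1) and AT3G62970 with NH4NO3 (0.76 ± 0.15, adjusted p = 1). Over all probe sets the smallest adjusted p with GSH was 0.222, in a probe set unnamed here. Limma called 0 probe sets for each solution, against 599, 506 and 611 at an unadjusted p under 0.05 for GSSG, GSH and NH4NO3. None of the 12 gene lists passed its test at 3W. Adjusted over the list alone, COR15B of the drought and cold list rose with GSH (0.92 ± 0.30, adjusted p = 0.0226). The senescence gene WRKY6 fell with GSH (-1.14 ± 0.40, adjusted p = 0.0473). Both were picked from their lists after their values were seen, and neither passed over all genes. Without 3W control replicate 2, limma called 1, 1 and 2 probe sets for the 3 solutions. Without 3W GSH replicate 2 it called 1 for GSH, and without 3W NH4NO3 replicate 1 it called 3 for NH4NO3.

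**Figure D1:**
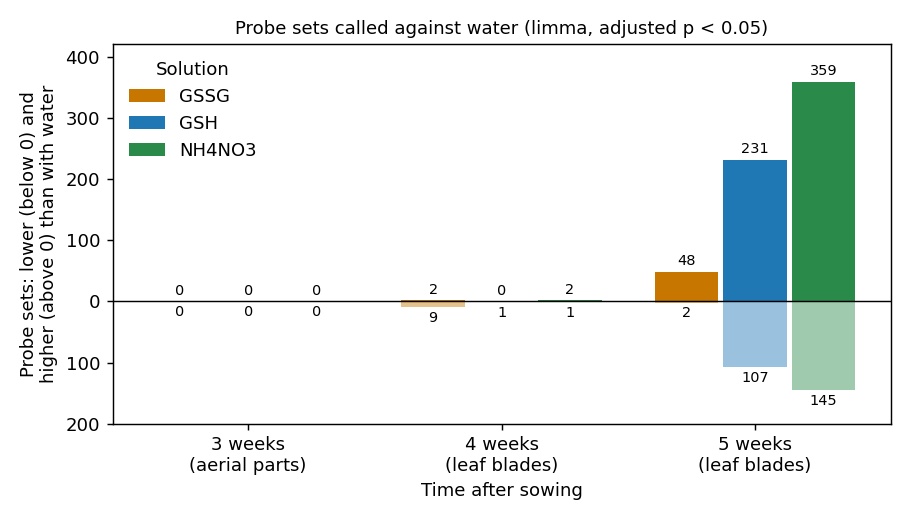
Number of probe sets called higher (bars above 0) and lower (paler bars below 0) than with water for each solution at each harvest, by limma at an adjusted p under 0.05. At 3 weeks the counts are 0, and at 5 weeks they are 48 and 2 for GSSG, 231 and 107 for GSH, and 359 and 145 for NH4NO3.

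In leaf blades at 4W a CC-type glutaredoxin stood out after NH4NO3. CC-type glutaredoxins are small plant-specific oxidoreductases related to glutathione-dependent enzymes. AT4G15700 (GRXS3) rose with NH4NO3 by 2.95 ± 0.42 (log2 change, adjusted p = 0.0127), from a signal of 29.6 ± 6.84 to 335 ± 45.7 (SD, n = 2). The 13 measured members of this group were higher with NH4NO3 by a median of 1.59, with 11 of 13 higher (camera adjusted p = 7.76e-11, and adjusted p = 0.000639 with an estimated correlation). Of them 1 rose over all genes, and 7 rose and 2 fell when adjusted over the list alone. Limma called 2 more genes for NH4NO3 at 4W: AT2G16660 rose by 1.64 ± 0.27 (adjusted p = 0.0447) and AT4G01390 fell by 1.97 ± 0.24 (adjusted p = 0.00278). The 4 measured glucosinolate genes were higher as a list (median 0.34, adjusted p = 0.0347, and adjusted p = 0.534 with an estimated correlation). So were the 3 iron genes (median 0.72, adjusted p = 0.0324, and adjusted p = 0.119 with an estimated correlation). In both lists 0 genes passed limma over all genes and 0 adjusted over the list alone. The count of 3 was 12 with a replicate block, 5 higher and 7 lower. It became 0 without 4W control replicate 1, 0 without 4W NH4NO3 replicate 1, 1 without 4W control replicate 2, 23 without 4W NH4NO3 replicate 2 and 0 with only the arrays compared. AT4G15700 and AT2G16660 lost their calls without each of the first 3 of these arrays and AT4G01390 without the first 2 (adjusted p up to 0.874), and AT4G15700 also with a pseudocount of 1 (adjusted p = 0.304).

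With GSSG at 4W, 9 probe sets fell and 2 rose. The largest falls were those of AT1G76960 (log2 change -2.54 ± 0.44) and AT3G63090 (-1.95 ± 0.35). They were followed by the CC-type glutaredoxin AT1G06830 (GRXS11; -1.46 ± 0.26) and the thaumatin family gene AT4G36010 (-1.45 ± 0.26), with an adjusted p of 0.0473 for each of these 4. The DEAD-box RNA helicase gene AT3G18600 fell by 1.18 ± 0.16 (adjusted p = 0.00871). No gene list passed at 4W with GSSG or GSH. With GSSG the drought and cold genes COR15A (-1.05 ± 0.39) and LTI30 (-0.93 ± 0.34) and the senescence gene WRKY53 (-1.22 ± 0.38) fell adjusted over the list alone (adjusted p = 0.028, 0.028 and 0.0215), and the Calvin cycle gene SBPASE rose with GSSG (0.81 ± 0.19, adjusted p = 0.00104) and GSH (0.52 ± 0.19, adjusted p = 0.0366). In these lists 0 genes passed over all genes. The GSSG count of 11 was 156 with a replicate block, 76 higher and 80 lower. It became 3 without 4W control replicate 1, 0 without 4W control replicate 2, 42 without 4W GSSG replicate 1, 0 without 4W GSSG replicate 2 and 0 with only the arrays compared. AT1G76960, AT1G06830 and AT4G36010 lost their calls without each of these 4 arrays, and AT3G63090 and AT3G18600 without each but 4W GSSG replicate 1 (adjusted p up to 0.549).

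With GSH at 4W limma called 1 probe set, which fell. It has no gene name here and was singled out after its value was seen (adjusted p = 0.00282). The named genes with the smallest p, AT1G68600 (-1.56 ± 0.26) and AT1G73600 (-1.89 ± 0.32), both had an adjusted p of 0.0521 and did not meet the rule. With a replicate block the count of 1 was 86, 27 higher and 59 lower. It became 11, 0 and 5 without 4W control replicate 1, 4W control replicate 2 and 4W GSH replicate 1, and 0 with only the arrays compared.

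At 5W, 48 probe sets rose and 2 fell in the leaf blades of plants fed GSSG. AT1G49500 rose by 3.61 ± 0.37 on the log2 scale (adjusted p = 0.000136), from a signal of 7.54 ± 0.70 with water to 272 ± 12.1 (SD, n = 2). Its signal with water lay under the 16 added before the log2 scale, so the size of its changes depends on that addition. No fold is given for a gene with a group under a signal of 100. AT5G19120 of the aspartyl protease family rose by 3.13 ± 0.53 (adjusted p = 0.01). AT3G08030, a cell wall protein gene of the DUF642 family, rose by 2.51 ± 0.29 (adjusted p = 0.00049). AT1G29670 of the GDSL lipase family rose by 2.15 ± 0.41 (adjusted p = 0.0275) and AT2G38820 by 1.82 ± 0.28 (adjusted p = 0.00489). AT1G15410 (-1.41 ± 0.27, adjusted p = 0.0283) and AT5G10770 (-1.36 ± 0.28, adjusted p = 0.0441) fell. AT1G25550 (HHO3), a nitrate-responsive repressor gene, rose by 1.36 ± 0.25 (adjusted p = 0.023). The 4 measured genes of anthocyanin synthesis were lower as a list (median -2.61, camera adjusted p = 2.64e-05, and adjusted p = 0.258 with an estimated correlation). Of them 0 passed limma over all genes and 3 fell adjusted over the list alone, and the GSSG arrays lay far apart (DFR signal 1112 ± 1502, SD). The 7 genes of light harvesting and the photosystems were higher (median 0.43, adjusted p = 0.00161, and adjusted p = 0.364 with an estimated correlation). The 4 genes of the abscisic acid, drought and cold list were higher too (median 0.48, adjusted p = 0.0274, and adjusted p = 0.368 with an estimated correlation). In these last lists 0 genes passed over all genes and 0 adjusted over the list alone. The count of 50 was 181 with a replicate block. It became 7 without 5W control replicate 2, 9 without 5W GSSG replicate 2 and 0 with only the arrays compared. AT1G49500 and AT3G08030 kept their calls without any 1 of the 4 arrays, AT5G19120 and AT2G38820 lost them without either array just named, AT1G29670, AT1G15410 and AT5G10770 without each but 5W control replicate 1, and AT1G25550 without each but 5W GSSG replicate 1 (adjusted p up to 0.672).

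With GSH at 5W, 231 probe sets rose and 107 fell, and genes of late anthocyanin synthesis had the largest falls among the named genes. DFR, which encodes dihydroflavonol reductase, fell by 6.17 ± 0.97 on the log2 scale (adjusted p = 0.00153), from a signal of 2638 ± 754 with water to 24.6 ± 26.3 with GSH (SD, n = 2). The anthocyanin glycosyltransferase genes UF3GT (-5.41 ± 0.80, adjusted p = 0.000945) and AT4G14090 (-4.54 ± 0.74, adjusted p = 0.0022) fell. So did the malonyltransferase gene AT5MAT (-2.71 ± 0.65, adjusted p = 0.0411) and the chalcone isomerase-like gene CHIL (-2.56 ± 0.52, adjusted p = 0.0146). All 4 measured members of the flavonoid and anthocyanin list fell, over all genes and adjusted over the list alone (camera adjusted p = 5.31e-11, and adjusted p = 0.0269 with an estimated correlation). AT1G49500 rose by 5.51 ± 0.37 (adjusted p = 6.92e-08) and AT5G19120 by 5.13 ± 0.53 (adjusted p = 1.36e-05). AT2G20670 rose by 4.27 ± 1.05 (adjusted p = 0.0458) and the legume lectin-type gene AT5G03350 by 3.79 ± 0.62 (adjusted p = 0.00234). EXPA8, an expansin that loosens cell walls, rose by 3.31 ± 0.49 (adjusted p = 0.000945). Of the nitrogen genes, AT1G25550 rose by 2.18 ± 0.25 (adjusted p = 6.06e-05) and its relative AT1G68670 (HHO2) by 1.55 ± 0.32 (adjusted p = 0.0168). The nitrate transporter gene AT2G26690 (NRT1.4) rose by 1.23 ± 0.28 (adjusted p = 0.0272). Of 3 glutathione genes GR1, a glutathione reductase, fell by 0.61 ± 0.15 (adjusted p = 0.0458), 1 gene over all genes and 1 adjusted over the list alone. With GSSG (-0.38 ± 0.15, adjusted p = 0.588) and NH4NO3 (-0.32 ± 0.15, adjusted p = 0.363) at 5W it did not pass, with 0 genes over all genes and 0 adjusted over the list alone. Over the mean of harvests 0 glutathione genes passed over all genes, and GR1 fell adjusted over the list alone with GSSG (-0.31 ± 0.09, adjusted p = 0.00579) and GSH (-0.26 ± 0.09, adjusted p = 0.0196), 1 gene each. The light harvesting list was higher, with 7 of 7 genes higher (median 0.59, adjusted p = 0.000827, and adjusted p = 0.325 with an estimated correlation). In it 0 genes passed limma over all genes and 3 rose adjusted over the list alone. Under quantile normalization the list's median with GSH at 5W shrank to 0.339. At 5W it shrank from 0.43 to 0.275 with GSSG and from 0.446 to 0.255 with NH4NO3. The size of this change thus depends on the scaling, while its sign was kept. The count of 338 was 897 with a replicate block. It became 66 without 5W GSH replicate 1, 101 without 5W control replicate 2 and 79 with only the arrays compared. DFR, UF3GT, AT4G14090, AT1G49500, AT5G19120, EXPA8 and AT1G25550 kept their calls without any 1 of the 4 arrays, AT5G03350 lost its call without either array just named, AT5MAT without each but 5W GSH replicate 1, CHIL, AT1G68670 and AT2G26690 without each but 5W GSH replicate 2, and AT2G20670 and GR1 without each (adjusted p up to 0.492).

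With NH4NO3 at 5W, 359 probe sets rose and 145 fell. AT1G49500 rose by 7.45 ± 0.37 (adjusted p = 3.86e-10), to a signal of 4121 ± 436 (SD, n = 2), and AT5G03350 rose by 6.41 ± 0.62 (adjusted p = 6.39e-06). AT5G19120 rose by 4.29 ± 0.53 (adjusted p = 0.000109), AT5G52760 by 3.22 ± 0.51 (adjusted p = 0.00115) and EXPA8 by 3.11 ± 0.49 (adjusted p = 0.00107). Of the nitrogen genes, AT1G25550 rose by 2.88 ± 0.25 (adjusted p = 2.44e-06), AT1G68670 by 1.78 ± 0.32 (adjusted p = 0.00354) and AT2G26690 by 1.78 ± 0.28 (adjusted p = 0.00101). NRT2.5, a high-affinity nitrate transporter known to be induced by nitrogen starvation, fell by 2.41 ± 0.50 (adjusted p = 0.0115), from 214 ± 7.25 to 28.0 ± 11.9. With GSSG and GSH its changes were -1.06 ± 0.50 and -1.17 ± 0.50 and did not pass over all genes (adjusted p = 0.715 and 0.339). Both passed adjusted over the list alone (adjusted p = 0.0477 and 0.031), where 2 of 2 nitrogen uptake genes passed with each solution, beside 0, 1 and 2 over all genes with GSSG, GSH and NH4NO3. All 4 anthocyanin genes fell, over all genes and adjusted over the list alone (camera adjusted p = 1.68e-07, and adjusted p = 0.0972 with an estimated correlation). They were DFR (-3.97 ± 0.97), AT4G14090 (-3.93 ± 0.74), UF3GT (-3.46 ± 0.80) and AT5MAT (-3.08 ± 0.65), with adjusted p from 0.0052 to 0.0337. AT3G62960, a CC-type glutaredoxin (GRXC14), fell by 2.54 ± 0.55 (adjusted p = 0.0148). The glucosinolate list was higher (median 0.49, adjusted p = 0.00615, and adjusted p = 0.315 with an estimated correlation), with 0 genes past limma over all genes and 1 risen adjusted over the list alone. The light harvesting list was higher (median 0.45, adjusted p = 0.0101, and adjusted p = 0.461 with an estimated correlation), with 0 genes over all genes and 3 adjusted over the list alone. The count of 504 was 1080 with a replicate block. It became 154 without 5W NH4NO3 replicate 1, 158 without 5W control replicate 2 and 227 with only the arrays compared. AT1G49500, AT5G03350, AT5G19120, AT5G52760, EXPA8, AT1G25550 and AT2G26690 kept their calls without any 1 of the 4 arrays, AT1G68670 lost its call without 5W NH4NO3 replicate 1, AT4G14090 and AT3G62960 without either array just named, AT5MAT, DFR and NRT2.5 without each but 5W NH4NO3 replicate 2, and UF3GT without each (adjusted p up to 0.362).

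**Figure D2:**
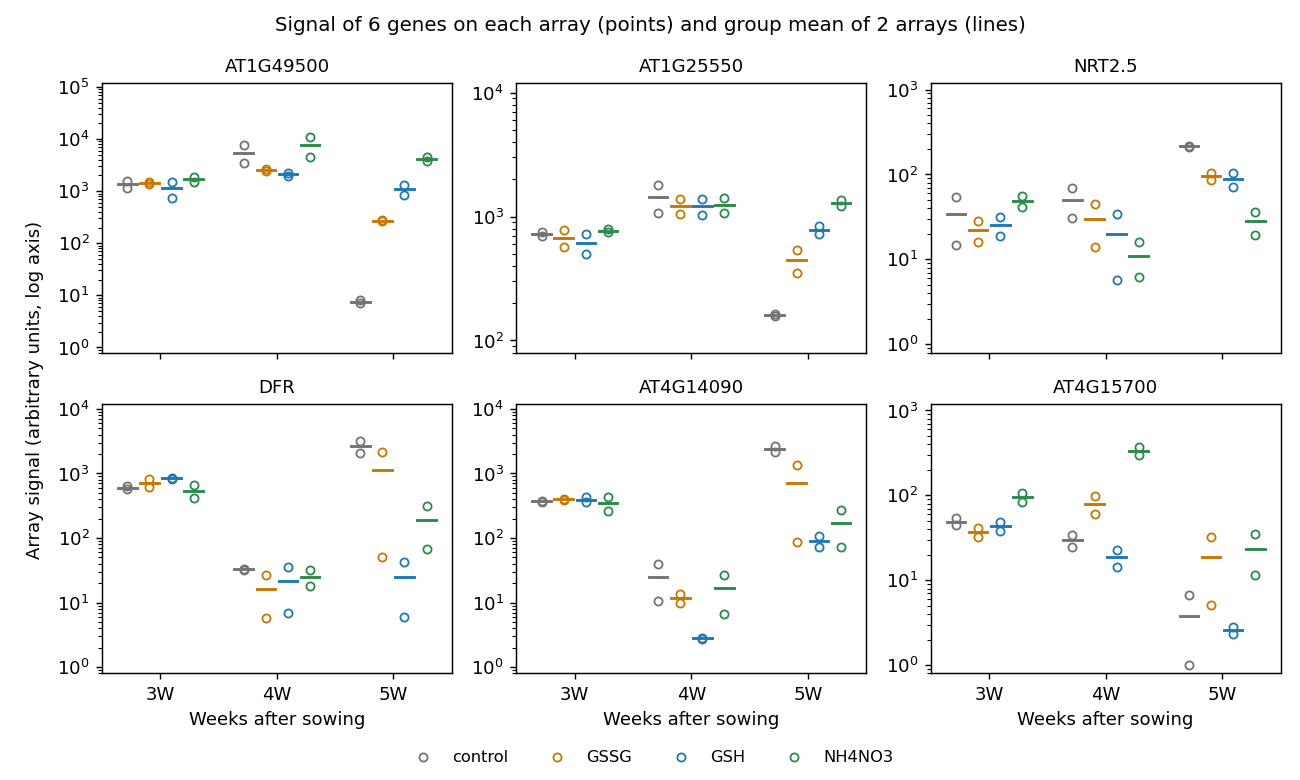
Deposited signal (arbitrary units, log axis) of 6 genes on every array (open points, 2 per group) with the group mean as a line, by weeks after sowing and watering. At 5W the water arrays of AT1G49500 and AT1G25550 lie below all 6 fed arrays, those of NRT2.5 and AT4G14090 above them, and the DFR signal of the GSSG arrays spreads widely (1112 ± 1502, SD).

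The genes called at 5W overlapped between solutions. GSSG and GSH shared 47 probe sets called higher and 2 called lower. GSSG and NH4NO3 shared 46 and 1, and GSH and NH4NO3 shared 155 and 55, with 0 called in opposite directions in any pair. Independent lists of these sizes would share 0.487 and 0.00941, 0.758 and 0.0127, and 3.65 and 0.682. Simulated unchanged groups that shared simulated water arrays had 0 in common. Every simulated array was drawn without effects, so almost nothing could be called and this 0 says nothing on the overlap. A deviation of the real water arrays common to many genes was not simulated. Across genes, which are not independent replicates, the covariance of the log2 changes was 0.127, 0.125 and 0.176 for the 3 pairs, against 0.0379, 0.0378 and 0.0381 in the simulation. The correlation was 0.809, 0.737 and 0.77, against 0.498, 0.499 and 0.5. With 1 of the 2 water arrays given to each side, the covariance was 0.0835, 0.0815 and 0.132 and the correlation 0.42, 0.383 and 0.491 at 5W.

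Over the mean of the 3 harvests, NH4NO3 raised 76 probe sets and lowered 34. The CC-type glutaredoxin AT4G15700 rose by 1.55 ± 0.24 (adjusted p = 0.00462). AT3G51450 (1.19 ± 0.26), AT2G05540 (1.05 ± 0.22), AT5G39590 (0.74 ± 0.10), AT5G52810 (0.68 ± 0.14) and AT2G03510 (0.55 ± 0.10) rose. CHIL (-1.52 ± 0.30), AT4G01390 (-1.18 ± 0.14), AT4G17670 (-0.98 ± 0.16), AT4G33040 (-0.97 ± 0.15), the sugar transporter family gene AT4G04750 (-0.74 ± 0.14) and AT3G18600 (-0.44 ± 0.09) fell. The adjusted p of these 12 genes lay between 0.00039 and 0.043. AT1G25550 (0.93 ± 0.14, adjusted p = 0.00421) and AT2G26690 (0.75 ± 0.16, adjusted p = 0.0357) rose too. As a list the CC-type glutaredoxins were higher with NH4NO3, with 10 of 13 higher (median 0.82, adjusted p = 0.00015, and adjusted p = 0.0263 with an estimated correlation). Of them 1 rose over all genes, and 7 rose and 2 fell adjusted over the list alone; without dim probe sets the list lost its call (adjusted p = 0.511). The anthocyanin list was lower (median -1.23, adjusted p = 0.000394, and adjusted p = 0.275 with an estimated correlation), with 0 genes past limma over all genes and 4 fallen adjusted over the list alone. The glucosinolate list was higher (median 0.28, adjusted p = 0.0139, and adjusted p = 0.339 with an estimated correlation), with 0 genes over all genes and 0 adjusted over the list alone. AT1G25550, AT4G01390, AT4G15700, AT4G17670, AT4G33040 and AT5G39590 kept their calls without any 1 of the 12 arrays. AT2G03510 lost its call without 4 of them, AT4G04750 without 6, CHIL without 8, AT2G05540, AT2G26690 and AT3G51450 without 9, AT5G52810 without 10 and AT3G18600 without each (adjusted p up to 0.165). With a replicate block the count of 110 was 445. It became 52 without 3W control replicate 1, 50 without 3W NH4NO3 replicate 1, 68 without 3W control replicate 2, 62 without 4W control replicate 2, 68 without 5W NH4NO3 replicate 1 and 52 without 5W control replicate 2.

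Over the mean of harvests GSH raised 40 probe sets and lowered 19. With 1 gene meeting the rule, the 5 with the smallest p are named without having met it. AT5G19120 rose by 2.12 ± 0.30, AT3G08030 by 1.12 ± 0.17 and AT2G38820 by 1.11 ± 0.16. AT4G37180, a MYB-related regulator gene, rose by 0.94 ± 0.14 and LCR69, a defensin-like protein gene, by 0.93 ± 0.14 (adjusted p of the 5 between 0.00288 and 0.0037). GSSG raised 1 probe set, unnamed here and singled out after its value was seen (1.46 ± 0.21, adjusted p = 0.0289). The named gene with the smallest p for GSSG was LCR69 (0.82 ± 0.13, adjusted p = 0.063). The CC-type glutaredoxins were lower as a list with GSH (median -0.33, adjusted p = 0.00626, and adjusted p = 0.095 with an estimated correlation). AT1G06830 fell by 0.82 ± 0.15 (adjusted p = 0.0246), 1 gene over all genes, and 4 fell adjusted over the list alone. AT1G06830 lost its call without 9 of the 12 arrays (adjusted p up to 0.127), and the 5 genes above kept theirs without any 1 of them. With GSSG the list was lower by a median of -0.24 (adjusted p = 0.025, and adjusted p = 0.31 with an estimated correlation), with 0 genes past limma over all genes and 1 fallen adjusted over the list alone. The anthocyanin list was lower with GSSG and GSH (median -0.83 and -1.69, adjusted p = 0.0305 and 5.11e-06, and adjusted p = 0.487 and 0.095 with an estimated correlation). In it 0 genes passed limma over all genes, and 0 and 4 fell adjusted over the list alone. The light harvesting list was higher with GSSG and GSH (median 0.26 and 0.23, adjusted p = 0.00166 and 0.00165, and adjusted p = 0.462 and 0.488 with an estimated correlation), with 0 genes over all genes and 0 adjusted over the list alone. With a replicate block the counts of 1 for GSSG and 59 for GSH were 106 and 340. The GSH count became 18 without 3W control replicate 1 or 3W GSH replicate 1, 29 without 3W control replicate 2, 27 without 3W GSH replicate 2, 37 and 20 without 4W control replicates 1 and 2, and 19 without 5W GSH replicate 1 or 5W control replicate 2, and the GSSG count became 12, 5 and 15 without 4W GSSG replicate 1, 5W control replicate 1 and 5W GSSG replicate 1, 2 without 3W control replicate 2, and 0 without 3W control replicate 1, 5W control replicate 2, either 4W control array or replicate 2 of GSSG at any harvest.

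GSSG and GSH differ by the disulfide bond and were given at equal glutathione units, and few differences between their transcripts were detected. Limma called 0 probe sets over the mean of 3 harvests, 0 at 3W and 0 at 5W, against 870, 660 and 893 at an unadjusted p under 0.05. At 4W it called 2, both lower with GSSG, unnamed here and singled out after their values were seen (log2 change -2.23 ± 0.34 and -1.85 ± 0.28, adjusted p = 0.0298 for both). Over the mean, the 95% interval of the difference had a median half-width of 0.28 on the log2 scale. For 98.4% of 13647 probe sets above the 40th percentile the whole interval lay within 1 of 0. At single harvests the half-width was 0.49 and the shares were 87.2% at 3W, 81.6% at 4W and 84.9% at 5W. The named genes with the smallest p did not meet the rule: at 5W AT1G49500 differed by -1.89 ± 0.37 (GSSG minus GSH, adjusted p = 0.631), and over the mean AT3G05760 by -0.43 ± 0.08 (adjusted p = 0.576). Over all probe sets the smallest adjusted p at 5W was 0.0762, in a probe set unnamed here. The anthocyanin list was higher with GSSG in 4 of 4 genes (median 0.86, adjusted p = 0.00484, and adjusted p = 0.861 with an estimated correlation), with 0 genes over all genes and 0 adjusted over the list alone. At 5W 0 of its 4 genes passed over all genes and 4 were higher with GSSG adjusted over the list alone: DFR (3.40 ± 0.97), UF3GT (2.89 ± 0.80), AT4G14090 (1.84 ± 0.74) and AT5MAT (1.44 ± 0.65), with adjusted p from 0.00462 to 0.0393. Adjusted over the list alone, APL3 of starch synthesis was higher (1.06 ± 0.24, adjusted p = 0.000698) and the nitrogen genes AT1G25550 (-0.82 ± 0.25, adjusted p = 0.00826) and AT1G68670 (-0.79 ± 0.32, adjusted p = 0.0228) were lower with GSSG at 5W, with 0 genes of these lists over all genes. At other harvests, adjusted over the list alone and with 0 over all genes, WRKY6 was higher with GSSG at 3W (1.25 ± 0.40, adjusted p = 0.0258), and SAG29 was higher (1.67 ± 0.52) and WRKY53 lower (-1.12 ± 0.38) at 4W (adjusted p = 0.0194 for both). ARR15 (0.85 ± 0.30, adjusted p = 0.0192) and APL3 (0.41 ± 0.14, adjusted p = 0.0183) were higher over the mean. These genes were picked from their lists after their values were seen. With a replicate block 5 probe sets were lower with GSSG at 5W, AT1G49500 among them (adjusted p = 0.0448), and 0 differed over the mean. The 2 calls at 4W became 23, 32, 0 and 0 without 4W GSSG replicate 1, 4W GSH replicate 1, 4W GSSG replicate 2 and 4W GSH replicate 2, and 10 and 1 were called at 5W without 5W GSSG replicate 2 and 5W GSH replicate 2.

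Glutathione of either form differed from NH4NO3, at equal nitrogen, in the CC-type glutaredoxins. Over the mean of harvests these were lower with GSSG than with NH4NO3 in 11 of 13 members (median -1.07, camera adjusted p = 3.99e-12, and adjusted p = 0.000369 with an estimated correlation). They were lower with GSH than with NH4NO3 in 11 of 13 members as well (median -0.80, adjusted p = 3.65e-13, and adjusted p = 0.000246 with an estimated correlation). The list was not tested between glutathione and NH4NO3 at single harvests. Against water it was called with NH4NO3 at 4W (median 1.59) and not at 3W or 5W, so the difference may not hold at each harvest. With GSSG 1 member was lower over all genes, AT4G15660 (GRXS8; -1.57 ± 0.31, adjusted p = 0.0428), and 9 adjusted over the list alone. With GSH 2 were lower over all genes, AT4G15700 (-1.75 ± 0.24, adjusted p = 0.0021) and AT4G15660 (-1.87 ± 0.31, adjusted p = 0.00882), and 7 adjusted over the list alone. AT4G01390 was higher with GSSG (1.05 ± 0.14, adjusted p = 0.00266) and with GSH (1.46 ± 0.14, adjusted p = 2.75e-05). AT1G63420 was higher with both as well (0.67 ± 0.10 and 0.58 ± 0.10, adjusted p = 0.00677 and 0.0166), and AT2G16660 was lower with both (-1.14 ± 0.15 and -1.40 ± 0.15, adjusted p = 0.00266 and 0.000142). AT3G19030 (-1.27 ± 0.24), AT5G52810 (-0.95 ± 0.14), PMEAMT, a methyltransferase of choline synthesis (-0.80 ± 0.14), and AT5G39590 (-0.59 ± 0.10) were lower with GSSG. AT5G45000 (-1.14 ± 0.23), AT4G34950 (-0.84 ± 0.15) and AT2G38180 (-0.82 ± 0.17) were lower with GSH. Between GSSG and NH4NO3, AT4G15660 lost its call without 9 of the 12 arrays, AT3G19030 without each, AT5G39590 without 7 and PMEAMT without 5 (adjusted p up to 0.167). Between GSH and NH4NO3, AT2G38180 lost its call without each of the 12 arrays, AT5G45000 without 10, AT1G63420 without 6 and AT4G34950 without 4 (adjusted p up to 0.191). The other named calls of these 2 comparisons were kept without any 1 array. The glucosinolate list was lower with both (median -0.26 and -0.38, adjusted p = 0.00707 and 0.000798, and adjusted p = 0.314 and 0.181 with an estimated correlation). In it 0 genes passed limma over all genes, and 1 and 2 fell adjusted over the list alone. In all, 6 probe sets were higher and 30 lower with GSSG than with NH4NO3, and 18 higher and 31 lower with GSH. With a replicate block the GSH count of 49 was 129, and with 3W and 5W alone the GSSG and GSH counts were 2 and 1. The GSSG count of 36 became 14, 17, 20, 18, 19 and 23 without 3W GSSG replicate 1, 3W NH4NO3 replicate 1, 3W GSSG replicate 2, 5W NH4NO3 replicate 1, 5W GSSG replicate 2 and 5W NH4NO3 replicate 2, and the GSH count became 22, 28, 32 and 28 without 3W GSH replicate 1, 3W NH4NO3 replicate 2, 5W NH4NO3 replicate 1 and 5W GSH replicate 2.

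Between 4W and 5W the leaf blades changed in 6746 probe sets, 3657 higher and 3089 lower at 5W over the 4 waterings (8 arrays against 8). The fit treats these arrays as independent, although same-numbered arrays of a harvest deviated together. The SE and p-values over the 4 waterings may therefore be too small. Fewer probe sets were called with a random replicate block, as given further below. The labels give nothing that would tell plant age apart from harvest day or array handling. The blades were chosen by position as fully expanded, so leaf age is here only a name for this difference between harvests. AT4G14090 of anthocyanin synthesis rose by 3.64 ± 0.37 (adjusted p = 4.76e-07). HIS1-3, a linker histone gene induced by drought, rose 7.33-fold (2.87 ± 0.17) and the glutaredoxin gene AT2G47880 (GRXC13) 6.15-fold (2.62 ± 0.28). STZ, a zinc finger repressor of stress responses, rose 5.29-fold, and SUFE2, a gene of iron-sulfur cluster assembly, 3.93-fold (1.97 ± 0.18). AT5G39520 (3.46 ± 0.43), AT2G17710 (2.59 ± 0.22), AT4G29700 (2.14 ± 0.26), AT4G38540 (2.12 ± 0.23) and AT4G27657 (1.93 ± 0.25) rose as well. AT5G12940 fell by 3.44 ± 0.28 (adjusted p = 3.71e-08). The GDSL lipase family genes AT4G18970 (-3.31 ± 0.35) and AT4G28780 (-3.01 ± 0.34), the thionin gene AT1G66100 (-2.91 ± 0.23) and AT3G10720 (-2.78 ± 0.25) fell. STOMAGEN, a peptide that promotes stomatal development, fell by 2.68 ± 0.20. AT2G34620 (-2.46 ± 0.11), SKU5, a gene of directional root growth (-2.36 ± 0.21), AT5G60800 (-2.34 ± 0.29) and AT1G04800 (-2.31 ± 0.16) fell too. The adjusted p of these 20 genes was at most 8.16e-06. The 4W arrays of replicate 2 were those with the high actin ratios, and without them 6627 probe sets were called.

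All 7 light harvesting and photosystem genes fell with leaf age, over all genes and adjusted over the list alone (camera adjusted p = 6.22e-06, and adjusted p = 0.16 with an estimated correlation). They included PSAN (-1.07 ± 0.13), PSBW (-0.82 ± 0.11), PSBY (-0.81 ± 0.11) and PSAE-1 (-0.77 ± 0.13). Under quantile normalization the list's median shrank from -0.769 to -0.459. Of 3 Calvin cycle genes SBPASE fell by 1.00 ± 0.09 and PRK fell by 0.65 ± 0.12, 2 over all genes and 3 adjusted over the list alone (list adjusted p = 0.00746, and adjusted p = 0.16 with an estimated correlation). All 4 anthocyanin genes rose, over all genes and adjusted over the list alone (list adjusted p = 0.000732, and adjusted p = 0.16 with an estimated correlation), with DFR at 2.87 ± 0.49, UF3GT at 2.36 ± 0.40 and AT5MAT at 0.97 ± 0.33. These are means over the 4 waterings, and the change within each was looked at after the values were seen. With water all 4 rose: AT4G14090 (5.98 ± 0.74), DFR (5.73 ± 0.97), UF3GT (5.37 ± 0.80) and AT5MAT (3.13 ± 0.65), with adjusted p at most 0.00377. With GSSG the first 3 rose. With GSH the changes were 2.48 ± 0.74 in AT4G14090 (adjusted p = 0.0608), 0.07 ± 0.97 in DFR, -0.29 ± 0.80 in UF3GT and 0.28 ± 0.65 in AT5MAT, and with NH4NO3 2.35 ± 0.74 (adjusted p = 0.0952), 2.04 ± 0.97, 1.67 ± 0.80 and -0.76 ± 0.65. None of these 8 passed, which does not show that the rise was absent. In the abscisic acid, drought and cold list LTI30 (1.43 ± 0.17), COR47 (0.98 ± 0.21) and COR15A (0.73 ± 0.19) rose, 3 of 4 genes over all genes and 3 adjusted over the list alone (list adjusted p = 0.019, and adjusted p = 0.262 with an estimated correlation). In the sulfate assimilation list the ATP sulfurylase genes APS4 (0.60 ± 0.08) and APS3 (0.30 ± 0.11) rose, 2 of 3 genes over all genes and 2 adjusted over the list alone (list adjusted p = 0.0466, and adjusted p = 0.16 with an estimated correlation). Of the nitrogen genes NRT2.5 rose by 1.39 ± 0.25, and AT1G25550 (-1.25 ± 0.12), AT2G26690 (-0.85 ± 0.14) and AT1G68670 (-0.60 ± 0.16) fell. Within waterings AT1G25550 fell with water (adjusted p = 3.69e-07) and with GSSG (-1.44 ± 0.25) and did not pass with GSH (-0.62 ± 0.25) or NH4NO3 (0.06 ± 0.25). NRT2.5 rose with water (1.86 ± 0.50, adjusted p = 0.0204), and its changes with GSH (1.63 ± 0.50), GSSG (1.36 ± 0.50) and NH4NO3 (0.70 ± 0.50) did not pass (adjusted p = 0.068, 0.0823 and 0.537). Of the sulfur deficiency markers AT1G04770 (SDI2) rose by 1.00 ± 0.15 and BGLU28 fell by 0.74 ± 0.27. Of the glutathione genes the reductase gene GR (-0.45 ± 0.08) and AT1G44790 (GGCT2;3, -0.26 ± 0.08) fell (adjusted p at most 0.0455 for these 8 genes). Between 3W and 4W tissue and age changed together, and 12724 probe sets were called, 5975 higher and 6749 lower at 4W.

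The few measured sulfur genes did not pass over all genes with feeding. They were 3 of 23 listed genes of sulfate uptake and assimilation and 2 of 13 deficiency markers. The rest of these lists was not tested, so a sulfur response cannot be ruled out. The sulfate assimilation genes APS4, APS3 and SIR and the deficiency markers AT1G04770 and BGLU28 were not called for any solution against water over all genes. Their changes at 5W ran from -0.44 ± 0.16 (APS4, NH4NO3, adjusted p = 0.219) to 0.96 ± 0.55 (BGLU28, GSH, adjusted p = 0.519). Adjusted over the list alone, APS3 rose (0.66 ± 0.22) and APS4 fell (-0.52 ± 0.16) with NH4NO3 at 4W, 1 and 1 of 3 assimilation genes (adjusted p = 0.0116 for both). APS4 also fell with NH4NO3 adjusted over the list alone at 5W (adjusted p = 0.0456) and over the mean of harvests (-0.34 ± 0.09, adjusted p = 0.00558), 1 of 3 genes each, and 0 of 3 with GSSG or GSH at any harvest. Adjusted over the list alone, APS4 was higher and SIR lower over the mean of harvests than with NH4NO3 in plants fed GSSG (0.28 ± 0.09 and -0.25 ± 0.10, adjusted p = 0.0257 and 0.0333) and GSH (0.33 ± 0.09 and -0.29 ± 0.10, adjusted p = 0.00819 and 0.0149), beside 0 of 3 over all genes. For the 2 deficiency markers the count adjusted over the list alone was 0 for each solution and harvest. Of 13 measured glutathione S-transferase genes 0 passed limma over all genes at 5W, and 0, 0 and 1 adjusted over the list alone with GSSG, GSH and NH4NO3 (list adjusted p = 0.892, 0.569 and 0.404). Of 5 leaf senescence genes 0 passed over all genes, and 0, 0 and 1 adjusted over the list alone (list adjusted p = 0.892, 0.973 and 0.175). Among 4 antioxidant genes TAPX, a thylakoid ascorbate peroxidase, rose with NH4NO3 at 5W by 0.76 ± 0.20 (adjusted p = 0.048), 1 gene over all genes and 1 adjusted over the list alone (list adjusted p = 0.609). With GSH at 5W (0.78 ± 0.20, adjusted p = 0.0517), with GSSG at 5W (0.61 ± 0.20, adjusted p = 0.409), with GSSG at 4W (1.06 ± 0.20, adjusted p = 0.0544) and with GSH at 4W (0.71 ± 0.20, adjusted p = 0.346) it did not pass over all genes. In each of these 4 comparisons, and over the mean of harvests with each solution, 0 genes passed over all genes and 1, TAPX, rose adjusted over the list alone (adjusted p from 0.000128 to 0.0242). At 5W APL3, a subunit gene of ADP-glucose pyrophosphorylase in starch synthesis, fell with GSH (-1.33 ± 0.24, adjusted p = 0.00643) and NH4NO3 (-1.06 ± 0.24, adjusted p = 0.0238), 1 gene over all genes and 1 adjusted over the list alone in each. The cytokinin response regulator gene RR16 fell with NH4NO3 at 5W (-1.77 ± 0.45, adjusted p = 0.0402), 1 of 2 cytokinin genes over all genes. ARR15 (-1.43 ± 0.52 with NH4NO3, -1.81 ± 0.52 with GSH) and RR16 with GSH (-1.49 ± 0.45) did not pass over all genes (adjusted p = 0.194, 0.0923 and 0.116). Adjusted over the list alone 2 of 2 fell with GSH (adjusted p = 0.0034 for both) and 2 of 2 with NH4NO3 (adjusted p = 0.00154 and 0.0117), beside 0 and 1 over all genes. TAPX, APL3, RR16 and ARR15 were picked from their lists after their values were seen. The markers of other tissues that could be measured were not called over all genes with any solution against water. They were AUR1 and CLV3 of dividing and meristem cells, AGL24 of flowering, GUT2 of secondary walls and EXPA7 and EXPA18 of roots. HSA32 of the heat response, PDF1.2 and JMT of jasmonate and GI of the clock were not called either. With NH4NO3 at 5W AGL24 changed by -1.21 ± 0.40 (adjusted p = 0.143) and GI by -0.54 ± 0.18 (adjusted p = 0.154). Over the mean of harvests GI changed by -0.27 ± 0.11 with NH4NO3 (adjusted p = 0.389). Each is the 1 measured gene of its list, so adjusting over the list alone corrects for nothing. These 3 results passed only in that way, which is no call. For the other genes of this group the count adjusted over the list alone was 0 against water.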

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

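The tests of the water arrays for GSSG and GSH, both tests of the glutaredoxins, all tests of the anthocyanin genes and the count over all 108 splits were chosen only after the result was seen.

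The effect of feeding in leaf blades differed between 5W and 4W by a test of the difference itself, in 2 probe sets for GSSG, 35 for GSH and 39 for NH4NO3. With a replicate block these counts were 44, 262 and 226. For GSSG, AT1G49500 differed by 4.60 ± 0.52 (log2, SE), and the other probe set is unnamed here and was singled out after its value was seen (2.18 ± 0.31, adjusted p = 0.0121). For GSH the difference was 6.78 ± 0.52 in AT1G49500, 4.52 ± 0.74 in AT5G19120, 4.46 ± 0.69 in EXPA8, 4.17 ± 0.60 in AT3G19030 and 3.15 ± 0.41 in AT3G08030. In UF3GT it was -5.67 ± 1.13 and in AT1G57770 -1.26 ± 0.25. For NH4NO3 the difference was 6.99 ± 0.52 in AT1G49500, 5.52 ± 0.88 in AT5G03350, 4.43 ± 0.74 in AT5G19120, 3.13 ± 0.41 in AT3G08030 and 3.06 ± 0.35 in AT1G25550. In AT1G15410 it was -1.88 ± 0.38 and in AT5G45360 -1.23 ± 0.23. The adjusted p of these genes lay between 6.69e-07 and 0.0496. AT1G49500 (with each solution), AT3G08030 (with GSH and NH4NO3), AT3G19030 (with GSH) and AT1G25550 (with NH4NO3) kept their calls without any 1 of the 8 arrays. With GSH, UF3GT lost its call without each of the 8, AT1G57770 without 6, AT5G19120 without 3 and EXPA8 without 1 (adjusted p up to 0.273). With NH4NO3, AT5G45360 lost its call without 7, AT1G15410 without 6, AT5G19120 without 4 and AT5G03350 without 2 (adjusted p up to 0.276). The GSSG count became 9 without 4W GSSG replicate 1, 7 without 5W control replicate 1, 5 without 5W GSSG replicate 1 and 1 without 5W control replicate 2 or 5W GSSG replicate 2. The GSH count became 20, 19, 14 and 22 without 4W GSH replicate 1, 4W control replicate 2, 5W GSH replicate 1 and 5W control replicate 2. The NH4NO3 count became 24, 21, 21 and 15 without 4W NH4NO3 replicate 1, 4W control replicate 2, 5W NH4NO3 replicate 1 and 5W control replicate 2.

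More probe sets were called against water at 5W than at 3W or 4W. For GSSG this order depends on the threshold. At an unadjusted limma p under 0.05, GSSG had 2237 probe sets at 4W and fewer, 1578, at 5W. GSH had 1857 and 2748 and NH4NO3 1498 and 3012. With a replicate block the GSSG counts were 156 at 4W and 181 at 5W. A single deviating water array at 5W was argued against as the whole cause for NH4NO3 and GSH. At least 158 and 101 probe sets were called without either water array. Both counts came without 5W control replicate 2 and lie far under 504 and 338, so a part played by that array stays open. For GSSG the explanation stays open as a whole: 61 and 7 were called without 5W control replicates 1 and 2, and 9 without 5W GSSG replicate 2. Without 4W control replicates 1 and 2, 3 and 0 were called with GSSG at 4W. A smaller spread at 5W would not raise its count, since the fit gives each probe set 1 SE at all harvests. Across genes, the effect of a solution at 5W correlated negatively with the change from 4W to 5W in plants given another solution, which shares no array with it (mean of 6 correlations -0.363, from -0.465 to -0.264, against 0.0934 for the effects at 3W). Feeding may, as 1 hypothesis beside these open explanations, hold back part of the change that leaf blades undergo from 4W to 5W, while a difference between the pots of the water plants and the fed plants stays open and untested.

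The CC-type glutaredoxins were lower with GSH than with NH4NO3 over the mean of harvests, and single harvests were not tested. Signal near background was argued against as the whole cause, since the 5 members above the 40th percentile alone gave a camera p of 7.08e-05. Cross-hybridization among the tandem copies on chromosome 4 was argued against too, since the 9 members outside that cluster gave 1.08e-05 (0.0014 with an estimated correlation). For NH4NO3 against water the same subsets gave 0.00209 and 0.000867 at 4W (0.0163 and 0.00881 with an estimated correlation), and over the mean of harvests 0.302 and 0.0827, which did not pass. As a hypothesis, the difference may be biological: over the mean the list was higher with NH4NO3 than with water (median 0.82) and lower with GSH than with water (median -0.33). Both the salt and glutathione may contribute. The list's call for GSH against water was lost with an estimated correlation, however, as was that for GSSG.

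The late anthocyanin genes were lower at 5W in fed plants, with both water arrays above all 6 fed arrays in 3 of 4 genes and above the 4 GSH and NH4NO3 arrays in 4. With GSSG none of them passed over all genes (adjusted p from 0.248 to 0.757). With an estimated correlation the list lost its adjusted call at 5W for GSSG and for NH4NO3. A single high water array was argued against for GSH and NH4NO3. Without either water array the list gave a camera p of at most 2e-08 and 9.2e-06 (0.00969 and 0.0313 with an estimated correlation). These p-values were not adjusted over the lists, so 0.0313 does not restore the call lost for NH4NO3. With NH4NO3 the median change was -3.38 and -3.80 without water array 1 and 2. The explanation stays open for GSSG (0.00119, and 0.0988 with an estimated correlation), although the median change with GSSG was -2.31 and -2.71. Lower RNA integrity in 1 set of arrays was argued against, since the actin ratios of 2 of 2 water arrays, 2.98 and 3.06, lay within those of the fed arrays, 2.65 to 3.11; of their GAPDH ratios 1.144 lay within and 1.202 just above those of the fed arrays, 1.022 to 1.197. An equal lowering at each harvest was argued against for GSH and NH4NO3. The list's effect at 5W minus that at 4W or 3W gave a camera p of at most 6.59e-10 and 1.26e-06 (0.00482 and 0.0191 with an estimated correlation). These p-values were not adjusted over the lists either. An equal lowering stays open for GSSG (0.000385, and 0.0709 with an estimated correlation), although the median difference was -2.16 from 4W and -2.87 from 3W. As a hypothesis, GSH and NH4NO3 may restrain anthocyanin synthesis that sets in between 4W and 5W, and a difference in light or age between pots stays open and untested.

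Other splits of the arrays within harvests were counted for each comparison over the mean of 3 harvests, 100 of the 108 possible with the real one. The draw was changed once after a first draw had been seen, so that it holds all 32 splits that part every same-numbered pair and the 4 that follow replicate number, and all 108 were counted later. The other splits leave same-numbered arrays together on a side. Among the 32 are splits that exchange the sides of a whole harvest. These keep the real grouping within each harvest, so an effect at 5W alone can raise their counts too. A share above 0.05 therefore cannot decide between chance and such an effect. No split was fitted with a replicate block. For GSSG against water 21 of 100 splits called as many as the real 1, with 9 at most among the others, and 8 of the 32 did, so chance cannot be excluded; over all 108 splits it was 23, with 21 calls at most. For GSH against water 3 of 100 called as many as the real 59, with 64 at most (74 over all 108), but 2 of the 32 did, a share above 0.05, so chance cannot be excluded. For NH4NO3 against water 4 of 100 called as many as the real 110, with 119 at most, but 2 of the 32 did, so chance cannot be excluded. For GSSG against GSH 100 of 100 called as many as the real 0, with 2 at most, which any split must reach, so this count says nothing on chance. For GSSG against NH4NO3, whose numbers were not taken to pair the samples, 6 of 100 called as many as the real 36, with 55 at most, so chance cannot be excluded. For GSH against NH4NO3 3 of 100 and 1 of the 32, the real one, called as many as the real 49. Both shares lie under 0.05, but they were not adjusted over the comparisons, so chance cannot be excluded. There the highest of the others, 90, came from a split by replicate number, and with a replicate block the real count was 129. For 5W against 4W 1 of 100 splits within solutions, the real one, called as many as 6746, with 5206 at most among the others. These splits moved arrays singly, although same-numbered arrays of a harvest deviated together, and the share was not adjusted over the comparisons. They therefore cannot exclude chance, and plant age and harvest day cannot be told apart.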

How the results depend on the processing

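Leaving out the 4W arrays of replicate 2, the 4W harvest, and the random block for leaf age were tests chosen only after the result was seen; the others were planned. The named genes gave 428 results with 7679 values under the alternatives, of which 7139 kept their side of the threshold, 477 lost their call, 63 gained one and 0 reversed. With a replicate block 404 kept their side, 0 lost their call and 24 gained one. Those 24 are results that did not pass in the main fit and were called when same-numbered arrays were paired. Of 30 list calls in 192 tests, 5 were kept with an estimated correlation, 25 without dim probe sets and 30 with a replicate block. The count for leaf age stayed within 1.5 times its value under each alternative, a random replicate block (4857) included. Of the named results for leaf age, 40 kept their side of the threshold with that random block and 4 lost their call. The counts that moved by more follow; the cause was not tested. Quantile normalization gave 2 for the GSSG mean and 4 for GSSG minus GSH at 4W. Median centring gave 3 for GSH at 4W and 1 for GSSG minus GSH at 5W. Without dim probe sets there were 7 for GSH at 4W, 1 for NH4NO3 at 4W and 9 for the GSSG mean. A pseudocount of 1 gave 9 for the GSSG mean, 1 and 6 for GSSG minus GSH at 3W and 4W and 5 for the GSSG effect at 5W minus that at 4W. A pseudocount of 64 gave 6 and 33 for GSSG at 4W and 5W, 4 for GSH at 4W, 6 for NH4NO3 at 4W, 0 and 33 for the GSSG and GSH means, 58 for GSSG minus NH4NO3 and 1 for the GSSG effect at 5W minus that at 4W. No intensity trend gave 0 and 14 for GSSG, 2 and 161 for GSH and 5 and 320 for NH4NO3 at 4W and 5W, and 0, 20 and 33 for their means. It gave 0 for GSSG minus GSH at 4W, 12 and 27 for GSSG and GSH minus NH4NO3, and 1, 17 and 9 for the effects of GSSG, GSH and NH4NO3 at 5W minus those at 4W. A robust prior gave 4 for GSH at 4W, 7 for the GSSG mean and 1 for GSSG minus GSH at 5W. A replicate block gave 156 and 181 for GSSG, 86 and 897 for GSH and 12 and 1080 for NH4NO3 at 4W and 5W, and 106, 340 and 445 for their means. It gave 5 for GSSG minus GSH at 5W, 161 and 129 for GSSG and GSH minus NH4NO3, and 44, 262 and 226 for the effects at 5W minus those at 4W. Only the arrays compared gave 0 and 0 for GSSG, 0 and 79 for GSH and 0 and 227 for NH4NO3 at 4W and 5W, 2 for the GSSG mean, 0 for GSSG minus GSH at 4W and 26 for GSH minus NH4NO3, with 4, 11 and 7 for the effects at 5W minus those at 4W. The 4W and 5W leaf blades only gave 52, 221 and 353 for the means, and 160 and 103 for GSSG and GSH minus NH4NO3. Without the 4W arrays of replicate 2 there were 529 for GSH at 5W, and 0 and 24 for the GSSG and GSH means. The 3W and 5W harvests only gave 36 for the GSH mean, and 2 and 1 for GSSG and GSH minus NH4NO3.

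Leaving out each array in turn leaves 1 array in a group, assumed to vary like the other groups. At 3W the counts ran from 0 to 1 for GSSG, 0 to 1 for GSH and 0 to 3 for NH4NO3, at 4W from 0 to 42, 0 to 11 and 0 to 23, and at 5W from 7 to 61, 66 to 246 and 154 to 454. The means ran from 0 to 15, 18 to 60 and 50 to 148. GSSG minus GSH ran from 0 to 0 at 3W and over the mean, 0 to 32 at 4W and 0 to 10 at 5W. GSSG minus NH4NO3 ran from 14 to 50 and GSH minus NH4NO3 from 22 to 48. The effects at 5W minus those at 4W ran from 1 to 9, 14 to 47 and 15 to 50, and leaf age from 5759 to 6734. Signal over background limits the rest: at least 39.4% of probe sets on each array lay under a signal of 100.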

Other observations

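The families and the chloroplast genome were tests chosen only after the data were seen, in a scan of 36 families. Genes of the chloroplast genome were lower at 3W with each fed solution, in 63 of 69 genes with GSSG, 58 with GSH and 66 with NH4NO3. The medians were -0.22, -0.17 and -0.30 on the log2 scale (camera adjusted p = 8.21e-13, 4.71e-09 and 1.12e-22). These calls were lost with an estimated correlation (adjusted p = 0.661, 0.73 and 0.124), and limma called 0 of the genes. At 5W with GSSG 47 of 69 were higher (median 0.10, adjusted p = 0.0349, and adjusted p = 0.846 with an estimated correlation). Over the mean of harvests 55 of 69 were lower with NH4NO3 than with water (median -0.15, adjusted p = 0.000109, and adjusted p = 0.597 with an estimated correlation). There 52 were higher with GSSG than with NH4NO3 and 50 with GSH (adjusted p = 0.0328 and 0.00515, and adjusted p = 0.893 and 0.818 with an estimated correlation). The 3 comparisons share the same 2 water arrays, whose medians lay 0.29 and 0.16 above the mean of all 3W arrays, while the fed arrays lay between -0.18 and 0.006.

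With leaf age, 40 of the 69 chloroplast genes fell and 1 rose (adjusted p = 4.19e-11, and adjusted p = 0.233 with an estimated correlation). Of 9 measured RPS genes of ribosomal proteins 7 fell (adjusted p = 0.000624, and adjusted p = 0.176 with an estimated correlation). Of 10 genes of RALF-like signalling peptides 5 fell (adjusted p = 0.00316, and adjusted p = 0.0894 with an estimated correlation). Of 15 IQD genes of calmodulin-binding proteins 5 fell and 1 rose (adjusted p = 0.0127, and adjusted p = 0.233 with an estimated correlation). Of 11 ATG genes of autophagy 5 rose (adjusted p = 0.0096, and adjusted p = 0.52 with an estimated correlation).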
